A study of Mus musculus with 14 samples.

How the data were processed

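The series profiled chromatin of mouse mammary cells by ChIPmentation, a form of chromatin immunoprecipitation in which sequencing adapters are inserted by a transposase while the chromatin is still on the beads. Its 14 samples fall into 8 groups by their titles. 4 groups of 2 samples each were precipitated for H3K27ac, a histone mark of active promoters and enhancers, from fetal mammary stem cells and from adult basal, luminal progenitor and mature luminal cells, and 2 input samples accompany them. The remaining groups come from PY230 tumors and hold 2 SOX10 ChIP samples, 1 control sample and 1 input sample. Per the labels' protocols, the tumor cells carried SOX10 fused to an AVI tag together with BirA, the enzyme that attaches biotin to that tag, and SOX10 was pulled down on streptavidin beads with added SDS washes.

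The values analysed were a list of 7929 regions for the PY230 SOX10 ChIP samples against the control, to which the labels of both ChIP samples refer. It is 1 list for the pooled samples, with a chromosome, a start, an end, a number and a signal value for each region. The H3K27ac groups and the tumor input were not analysed here. FastQC, Bowtie 0.12.8, SAMtools 1.3.1 and MACS2 2.1.1 and the mouse build mm9 are named in the submitters' processing notes, without parameters. The threshold for calling a region, the treatment of duplicate reads and the formula of the signal are not given in the sources used here. Coordinates are those of the deposited list, written with 1-based starts. The last region on chromosome 1 ends at 197068022, past the last gene of that chromosome in the GRCm38.p6 gene table used for comparison.

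The deposited signal ranged from 0 to 0.735 and its unit is not stated. Among 7282 regions under 1500 bp with a signal above 0, signal times width was within 0.05 of a whole multiple of 0.0479 in 100% of regions, where a step chosen at random would give 10%. The step was searched for between 0.001 and 1, and no larger step gave more than 68.9%. The deposited signal therefore has the form of a mean coverage per base in which each base of a read adds 1 step. In 39.2% of these regions the multiple was itself a multiple of 54, against a median of 97 regions for the other lengths from 40 to 70 (2856 regions at 54). Read equivalents below are signal times width, divided by the step and by 54, and are a reading of the values, not reads counted by the authors. Whether a control was subtracted is not known, so they may be net of a control. The file gives no library totals, so the depth of each sample is unknown and no interval or floor was computed from it. The inverse of the step is 20.9. If the step came from scaling by a library total, 20.9 would be that total in the unit of the scaling. That scaling is not stated, and read equivalents were not compared with even background coverage of the genome. Whether they exceed such a background is therefore open. Of the 582 regions of 1500 bp or more, 70.4% came out as whole multiples.

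The number of regions on each chromosome was compared with the chromosome's share of the summed length by a two-sided exact binomial test with Benjamini-Hochberg adjustment over 20 chromosomes. The largest end coordinate on a chromosome stood for its length, since no mm9 sequence was used here. Intervals of regions per Mb are exact Poisson intervals at 95%. The number of neighbouring regions with a gap under 10 kb was compared with 10000 uniform random placements of the same regions on the same chromosomes, in a one-sided permutation test whose smallest p is 0.0001. Width and signal were correlated across regions with 95% bootstrap intervals. These tests describe 1 list. They treat regions as the unit and say nothing about the spread between the ChIP samples. Regions named in the text are the 20 with the highest signal and the highest of each chromosome, and the runs with the most regions were named after their values were seen.

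Regions were not assigned to genes. The gene table at hand was of GRCm38.p6, another build than that of the list, and coordinates were not converted. The planned tests of distance to transcription start sites, of 13 gene lists and of the SOX motif (3 of 6 planned tests) were therefore not run. Alternatives fixed before the data were examined were the 50% and the 10% of regions with the highest signal, runs within 10 kb counted once, the span of the regions as length, other gap limits, and other sets or scales for the correlation. Alternatives added later were a permutation of windows of about 10 Mb between chromosomes (10000 orders with the observed one), random moves of each region within its own 1 Mb window, the list without regions at 0 and the top 1%, and regions under 1500 bp only. The windows were first taken as whole windows of 10 Mb, which left out chromosome ends and with them part of the regions of chromosome 11. After that result had been seen they were replaced by equal windows covering each chromosome to its end, and both versions are given.

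The statistics were tested on simulated lists of the same 7929 regions. In 20 simulated lists with 3 changed chromosomes each, the binomial test recovered 60 of 60. In 20 lists without a change it called 0 of 400 chromosomes. The placement test called 0 of 20 uniform lists. The change-point test, added after the data were seen and repeated under 10 random seeds, found 20 of 20 simulated steps of 0.5 (log2). It called 0 of 20 series of 500 values without a step, where the real chromosomes had 48 to 267 runs. In the lists without a change and in the series, regions and values were drawn independently of each other. These counts therefore do not give the rate of false calls for regions as clustered as the real ones. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.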

Results

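To find where the transcription factor SOX10 binds in a mammary tumor model, the study pulled down biotin-tagged SOX10 from PY230 tumors, grown from transplanted PY230 mouse mammary tumor cells. SOX10 is an HMG-box factor known from the neural crest and its glial and melanocyte derivatives. The deposited list for both SOX10 ChIP samples against the control held 7929 regions on 20 chromosomes (1 to 19 and X). Their median width was 683 bp (quartiles 491 and 978, range 98 to 9185), and together they covered 6.33 Mb, or 0.242% of the summed chromosome length. The median signal was 0.0280 (quartiles 0.0200 and 0.0374). In read equivalents the median region had a value of 7.5 (quartiles 4.22 and 12.1), and 64.7% of regions had a value under 10. Whether these values exceed even background coverage was not tested. The list is a single pooled result, so no value below has a replicate error, and intervals cover counting error or resampling of regions only.

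SOX10 ChIP regions were spread unevenly over the chromosomes. Chromosome 4 was the densest, with 835 regions or 5.39 per Mb (95% interval 5.03 to 5.77), against 3.03 per Mb in the whole list. Chromosomes 19, 15, 13, 11 and 18 followed with 5.17, 5.15, 4.98, 4.62 and 4.42 regions per Mb. These 6 chromosomes held 40.7% of the regions on 24.8% of the length. Chromosome X was the sparsest, with 74 regions or 0.457 per Mb (0.359 to 0.574), which was 0.143 of the autosomal density of 3.20 per Mb.

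Against the share of length, 7 chromosomes held more regions than expected and 11 held fewer at an adjusted p under 0.05 in the exact binomial test. The observed number was 1.78 times the expected on chromosome 4 (adjusted p = 7.93e-55), 1.70 times on chromosome 19 (2.80e-18), 1.70 times on chromosome 15 (7.51e-30), 1.64 times on chromosome 13 (1.94e-29), 1.52 times on chromosome 11 (3.81e-21) and 1.46 times on chromosome 18 (2.01e-12, all in the exact binomial test). On chromosome 1 it was 1.09 times (0.0316), and the call did not hold when runs of nearby regions were counted once (exact binomial test, adjusted p = 0.0968). Chromosomes 3 and 9 lost their call in the same way (exact binomial test, adjusted p = 0.259 and 0.114), and chromosome 5, at 0.970 times the expected number, lost it among the 50% of regions with the highest signal (adjusted p = 0.659). The 10 autosomes below expectation (2, 3, 5, 6, 7, 8, 9, 14, 16 and 17) held 2.1 to 2.67 regions per Mb, and the number on chromosome X was 0.151 times the expected (1.41e-125). Chromosomes 10 and 12 did not pass the test, with 3.28 and 2.74 regions per Mb.

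Neighbouring regions are not independent, and these p-values are too small for that reason. When windows of about 10 Mb were exchanged between chromosomes, 1 chromosome stayed above (chromosome 4, adjusted p = 0.019) and 1 below (chromosome X, adjusted p = 0.002), in a permutation test added after the data were seen. Chromosomes 11, 13, 15 and 19 then each had an adjusted p of 0.0957 in this permutation test, and chromosome 18 had 0.166. A first version with whole windows only, which left out chromosome ends, kept 5 chromosomes above (4, 13, 15, 18 and 19) and 1 below, with chromosome 11 at 1.01 times the mean.

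**Figure D1:**
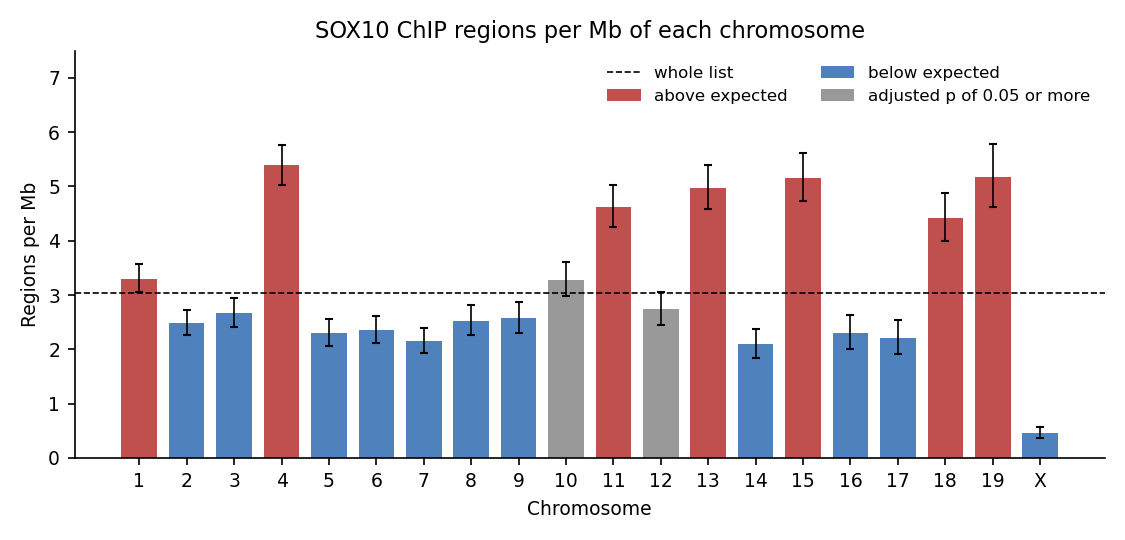
Bars give the number of SOX10 ChIP regions per Mb of each chromosome, with exact 95% Poisson intervals, coloured by the call of the exact binomial test, and the dashed line marks the density of the whole list. Chromosome 4 stands highest at 5.39 per Mb and chromosome X lowest at 0.457 per Mb.

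Median signal per chromosome ranged from 0.0231 to 0.0383, a spread that was described and not tested. It was highest on chromosome 4 (0.0383, quartiles 0.0284 and 0.0486), followed by chromosome 11 (0.0343, quartiles 0.0230 and 0.0468) and chromosome 5 (0.0325, quartiles 0.0247 and 0.0416). Chromosome 3 had the lowest median (0.0231, quartiles 0.0164 and 0.0314). Of the 793 regions that made up the 10% with the highest signal, chromosome 4 held 215 or 27.1%, and chromosome 11 held 131 or 16.5%. Chromosome 4 thus held 4.57 times, and chromosome 11 3.55 times, the number expected from length in this set (adjusted p = 9.92e-79 and 7.10e-35, exact binomial test). These p-values are too small as well, since the regions of this set are not independent. It held 148 neighbouring pairs less than 10 kb apart, 24.4 times the number under uniform placement. Windows were not exchanged and runs were not counted once for this set. Chromosomes 13 and 18 were above expectation in the whole list, yet held 0.811 and 0.853 times the expected number in this set (exact binomial test, adjusted p = 0.337 and 0.519).

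Along chromosome 11, the windows of 10 Mb from 0 to 110 Mb held 11 to 49 regions each, with median signals of 0.0238 to 0.0326. The window from 110 to 120 Mb held 205 regions with a median of 0.0458, and the rest of the chromosome held 40 with a median of 0.0466. On chromosome 4, the 12 windows up to 120 Mb held 8 to 126 regions and had median signals of 0.0361 to 0.048. The 4 windows beyond 120 Mb held 7 to 22 regions, with medians of 0.0201 to 0.0275. Chromosome 13 had windows of 12 to 86 regions with medians between 0.0257 and 0.0329.

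**Figure D2:**
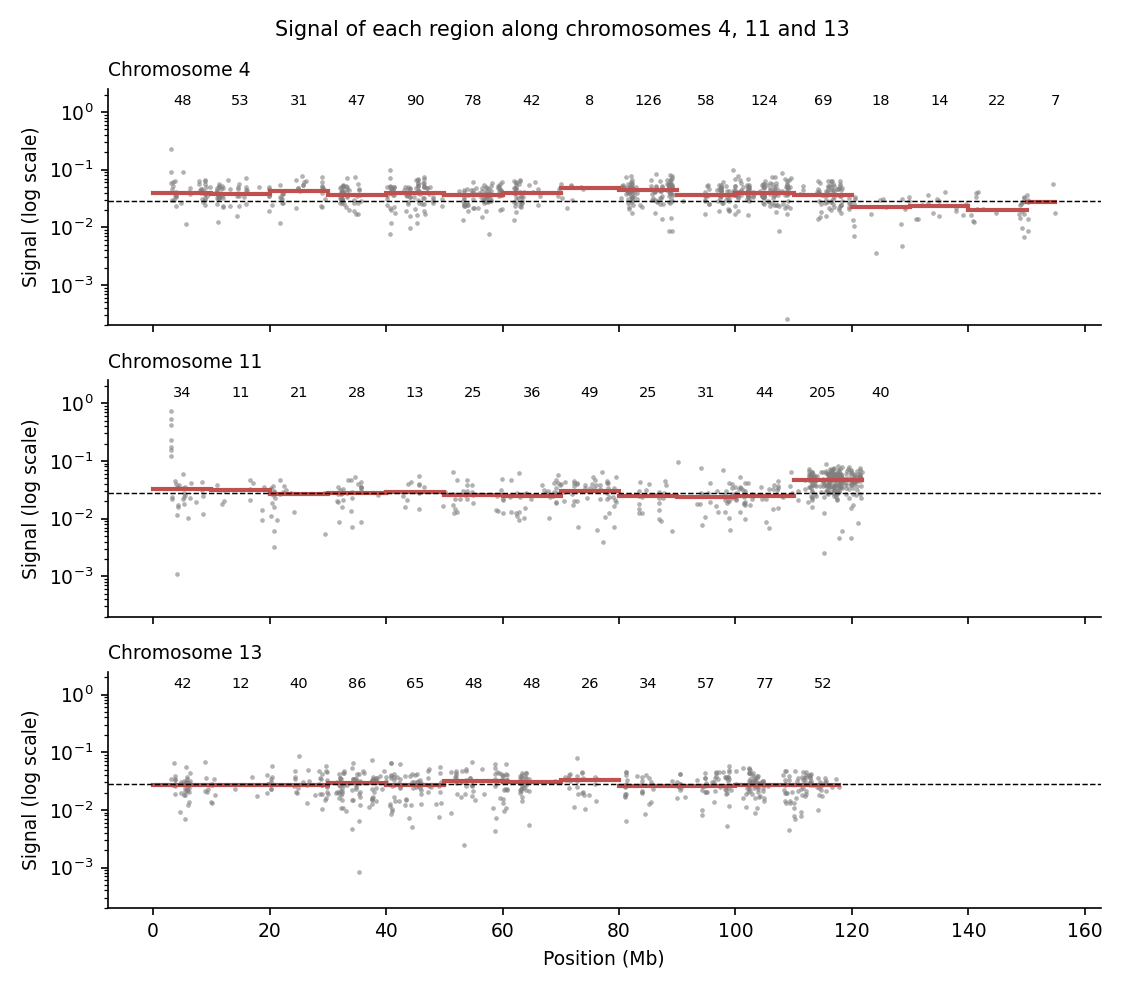
Each point is a region with a signal above 0 at its position in Mb on chromosome 4, 11 or 13, with signal on a log scale, red lines give the median of each 10 Mb window, numbers count its regions, including those at 0, and the dashed line marks the list median of 0.0280. Points and medians drop beyond 120 Mb on chromosome 4 and rise beyond 110 Mb on chromosome 11, where the window from 110 to 120 Mb holds 205 regions.

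SOX10 ChIP regions lay in groups. The median gap between neighbours was 61.3 kb (quartiles 12.4 and 261), and 1798 of 7909 neighbouring pairs (22.7%) were less than 10 kb apart. Uniform placement gave 299 such pairs ± 16.5 (SD over 10000 placements), so the observed number was 6.0 times as high (one-sided permutation p = 0.0001, the smallest possible). With each region moved only within its own 1 Mb window, placement gave 639 ± 22.2 pairs and the ratio was 2.81, which again exceeded all 10000 placements (one-sided permutation p = 0.0001). Gaps under 1 kb separated 455 pairs (5.75%), 8.85 times the number under uniform placement on whole chromosomes. The list does not show whether regions this close are separate sites.

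Joining regions less than 10 kb apart gave 6131 units, of which 4906 were single regions and 1225 were runs of at least 2. The runs took in 3023 regions, or 38.1% of the list. The run with the most regions, on chromosome 4 from 82139982 to 82189532, held 16 regions over 49.6 kb with a median signal of 0.0483. The next were a run of 12 regions on chromosome 11 (116937932 to 116982802, median signal 0.0523) and one of 11 on chromosome 4 (88680083 to 88725015, median signal 0.0457). A further run on chromosome 4 (88573736 to 88606858) held 8 regions. Of 56 runs with 5 or more regions, 15 lay on chromosome 4 and 10 on chromosome 11. Chromosome 6 held runs of 9 regions (47610742 to 47635572) and 7 regions (47687300 to 47708071) with median signals of 0.0784 and 0.0964. Among the 20 runs with the most regions, the highest median was 0.233, in a run of 7 regions on chromosome X (123300018 to 123309417). Regions in runs of at least 2 had a median signal of 0.0292 (quartiles 0.0210 and 0.0390), against 0.0274 for single regions (quartiles 0.0194 and 0.0364). In runs of 5 or more the median was 0.0378 (quartiles 0.0267 and 0.0529, 351 regions). Outside chromosomes 4 and 11, which have the highest median signals, it was 0.0306 in such runs (quartiles 0.0214 and 0.0477, 182 regions) and 0.0264 for single regions (quartiles 0.0188 and 0.0348). These differences were not tested.

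The 20 strongest regions lay far above the list median, with no gap to the regions ranked below them. Their signals of 0.269 to 0.735 were 9.60 to 26.2 times the list median, where 1% of the list lay above 0.0972. The highest was a region of 267 bp on chromosome 11 (3031410 to 3031676, signal 0.735), followed by regions on chromosome 16 (11144009 to 11144423, signal 0.626), chromosome 17 (3081520 to 3082169, signal 0.559) and chromosome 11 again (3044330 to 3045536, signal 0.533). Chromosome 1 held the fifth (85247375 to 85247525, signal 0.476), and chromosome 2 the sixth (5300195 to 5300416, signal 0.472). The 20 regions were narrow, with a median width of 256 bp (12 under 300 bp).

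6 of the 20 lay within 100 kb of position 3000000, at the start of the listed sequence of chromosomes 6, 11 and 17. Of the other 7909 regions, 14 did (two-sided Fisher's exact test, p = 4.27e-12, chosen after the positions were seen). The 6 regions belong to 4 runs and are not independent, so this p is too small. The strongest region of chromosome 4 was also there (3092322 to 3092503, signal 0.227). The strongest regions of chromosomes 9, 10, 12 and 13 had signals of 0.0735, 0.0777, 0.0881 and 0.0867, all below the 20 strongest of the list.

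Signal depended little on region width across the list. Spearman's rho was 0.160 (95% bootstrap interval 0.138 to 0.182) and Pearson's r was 0.032 (0.0085 to 0.059) over 7929 regions, which are not independent replicates. In 5 width classes of nearly equal size, the narrowest regions (98 to 450 bp) had a median signal of 0.0254 (quartiles 0.0162 and 0.0371), and the widest (1072 to 9185 bp) had 0.0315 (quartiles 0.0245 and 0.0398). Among the 50% of regions with the highest signal the sign turned, with rho at -0.0819. A group of 65 regions (0.820%) was listed at a signal of 0. They lay on 19 chromosomes and had a median width of 316 bp, against 687 bp for the regions above 0.

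**Figure D3:**
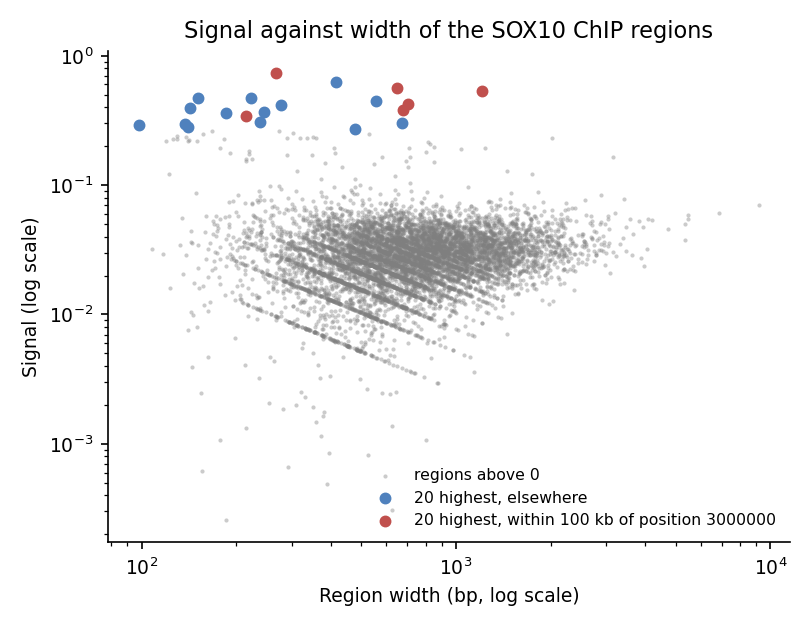
Each point is a region with a signal above 0, by width in bp and signal, both on log scales, and larger points are the 20 highest signals, in red where they lie within 100 kb of position 3000000. The 20 highest signals sit at 0.269 or above with a median width of 256 bp, and the slanting lines of points at low signal are whole numbers of read equivalents.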

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

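No paired analysis was possible because the list is 1 result for the pooled ChIP samples and carries no sample numbers. No library could be left out for the same reason. Among the 10% of regions with the highest signal, 3 chromosomes were called above expectation instead of 7. Chromosomes 13 and 18 lost their call at 0.811 and 0.853 times the expected number (exact binomial test, adjusted p = 0.337 and 0.519). Chromosomes 1 and 15 lost theirs at 1.14 and 1.27 times (exact binomial test, adjusted p = 0.331 and 0.161). Chromosomes 5, 6, 8 and 17 lost their call below expectation. Chromosomes 10 and 12, not called in the whole list, were called below expectation among these 10%. They held 0.360 and 0.519 times the expected number (exact binomial test, adjusted p = 1.13e-05 and 0.00277). Both were also below among the 50% with the highest signal, at 0.833 and 0.716 times (exact binomial test, adjusted p = 0.0177 and 5.02e-05). With windows of about 10 Mb exchanged between chromosomes, 1 chromosome was above and 1 below, against 7 and 11. With whole windows only, which left out chromosome ends, 5 were above and 1 below. Of 18 chromosomes called in the main test, 18 kept their call with the span as length, 17 among the 50% with the highest signal, 17 without regions at 0 and the top 1%, and 15 with runs counted once. Among the 10% with the highest signal 10 kept it, 6 lost it on the same side of expectation, and 2 (chromosomes 13 and 18) changed side. The excess of close neighbours passed its test under all 7 alternatives, with ratios from 2.81 to 24.4. The correlation of width and signal changed sign among the 50% with the highest signal (rho -0.0819, r -0.0875). Pearson's r became 0.0090 without the widest 1%, 0.152 on log2 signal, 0.164 without regions at 0 and the top 1%, and -0.024 under 1500 bp, where rho was 0.117. The cause was not tested. The low signal, with a median of 7.5 read equivalents per region, limits the ranking of single regions. It was not compared with background coverage, so a high rank by signal is no measure of binding above background. The alternatives without regions at 0 and the top 1%, with exchanged windows, with moves within 1 Mb and under 1500 bp were chosen after seeing the data.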

Other observations

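The change points and the tests on the steps, the chromosome starts and the regions at 0 were chosen after the list had been seen. Signal changed along some chromosomes beyond what shuffling runs of regions within a chromosome gave. In a rank-based change-point test with 10000 orders of runs within 100 kb, adjusted over 20 chromosomes, chromosome 4 split between 117960047 and 118081707 and chromosome 11 between 110820738 and 111905619 (permutation test, adjusted p = 0.000667 for both). On chromosome 4 the 762 regions before the split had a median signal of 0.0392 and the 73 after it 0.0239, with 6.63 and 1.98 regions per Mb. On chromosome 11 the 319 regions before the split had a median of 0.0265 and the 243 after it 0.0462, with 2.96 and 24.9 regions per Mb. Chromosome 15 split between 80961007 and 81077969 (median 0.0293 before and 0.0219 after, permutation test, adjusted p = 0.000667). Its densities were 5.52 and 4.60 regions per Mb, a smaller difference than on chromosomes 4 and 11. These 3 splits passed under 10 of 10 further random seeds. A split on chromosome 8 near 84.1 Mb (0.0231 and 0.0281) passed under 5 of the 10 seeds, with adjusted p from 0.0405 to 0.053 in the permutation test, and is not counted as a step. None of the other 16 chromosomes passed under any of these seeds, chromosome 9 coming closest (permutation test, adjusted p from 0.05 to 0.0616).

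Windows of 10 Mb with at least 20 regions and a median signal of 1.5 times the list median or more numbered 6 of 174. They lay on chromosome 1 from 80 to 90 Mb (64 regions, median 0.0467), on chromosome 4 from 20 to 30 Mb and from 80 to 90 Mb, on chromosome 6 from 40 to 50 Mb (32 regions, median 0.0563) and on the end of chromosome 11. The chromosome 1 window was uneven, with signal quartiles of 0.0256 and 0.124. The rise in that window came from a local group of regions around 85247375 to 87388980. This group included ranks 5, 7 and 12 of the 20 strongest. The other regions of the window lay lower, so the signal was not raised along all 10 Mb. The chromosome 6 window was uneven too, with quartiles of 0.0283 and 0.0941. Over 20 chromosomes, regions per Mb and median signal had a Spearman rho of 0.520, and of 0.366 without chromosomes 4 and 11.

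The steps on chromosomes 4 and 11 join higher signal with denser regions. On chromosome 15 the density differed less, and that step was not included in the tests below. Dense runs of strong regions are argued against as the whole cause, since regions with no neighbour within 10 kb shifted by 0.64 (log2, 95% interval 0.44 to 1.17) on chromosome 4 and 0.75 (0.58 to 0.94) on chromosome 11. Wider regions are likewise argued against, as the shift within 5 width classes was 0.77 (0.52 to 1.01) and 0.73 (0.60 to 0.88). Both shifts were taken across splits placed by the signals of these same regions, and their intervals make no allowance for that choice. A gain of DNA copies on one side in the tumor cells is a candidate explanation that stays open: the upper quartile shifted less than the lower, by -0.21 (-0.50 to 0.0089) and -0.30 (-0.48 to -0.11), where a pure scaling predicts 0 only if no calling threshold cuts the list. With signals scaled to equal medians, regions per Mb above the low side's upper quartile were 2.96 and 4.56 times as dense on the high side, which follows the density step itself and decides nothing about copy number; regional binding by SOX10 is open too, and the tumor input was not used here.

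The 6 strongest regions near position 3000000 raise the question of repeated sequence next to the centromeric gap of the mouse assembly, where reads from many copies may pile up. Outside the 20 strongest, the 14 regions within 100 kb of that position had a median signal of 0.130, or 4.64 times that of the rest. This met the bound of 1.5 times that was set for repeated sequence before the test was run (one-sided permutation p = 0.0001). However, 7 of the 14 share a run with regions of the 20, so this value largely restates the pattern. The 7 others, on 6 chromosomes, had signals of 0.0191 to 0.227 and a median of 0.0405. This was 1.45 times that of the rest (95% bootstrap interval 1.22 to 2.02, one-sided permutation p = 0.0308). The bound of 1.5 was applied to these 7 only afterwards and lies inside the interval, so repeated sequence as the cause stays open. Narrow width stays open too: signal times width in the 20 strongest was 5.68 times the list median (3.74 to 11.7), above the upper quartile at 1.61, but picking the highest signals after pairing these products with widths at random gave 7.88 to 13.4 times, so the value decides nothing. The 264 other regions of at most 256 bp had a median 1.02 times that of the list. Of these, 7.20% lay above the signal that 1% of the list exceeded. The other 14 of the 20 lie elsewhere, with no biological explanation tested. They include ranks 5, 7 and 12, which lie in the local groups on chromosome 1 described above.

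The 65 regions listed at 0 are hard to reconcile with a signal taken from the reads on which they were called. Subtraction of a control scaled by another factor was considered for regions under 1500 bp, where 100% of those above 0 were whole multiples of 1 step. The step was chosen from these same values as one that nearly all of them follow, so the 100% is no independent test. That such a step exists, where a random step would give 10%, argues only against a factor that leaves no common step. A control on the same scale, or a signal from other reads than those used for calling, was not tested. A further 57 regions above 0 came to less than 1 read equivalent, and the lower quartile of the whole list was 4.22. Low values are thus not confined to the regions at 0. What the signal measures in the remaining regions is not settled here either.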
